A study of Homo sapiens with 18 samples.

How the data were processed

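HEK293 cells, a human embryonic kidney line, were treated in culture for 90 min, per the labels, and polyadenylated RNA was measured by 3' tag sequencing (QuantSeq FWD libraries), in which each read comes from near the 3' end of a transcript. The 18 libraries form 6 groups of 3. Isoproterenol (Iso, 100 nM), an agonist of β-adrenergic receptors, was set against 1 µM ascorbic acid. NECA (20 µM), an agonist of adenosine receptors, was set against 0.05% DMSO. Vasoactive intestinal peptide (VIP, 500 nM) was set against a control that the series design calls water and the sample labels call no treatment, so what those 3 control cultures received is not settled. The labels give no time for this control. The series design states that the triplicates are biological. The labels do not say what a replicate number shares between groups.

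The deposited raw counts are whole numbers per gene and library. The submitters' processing notes name STAR 2.7.9a, the GRCh38 build, edgeR 3.36.0, limma 3.50.0 and R 4.1.0 without a role or order, and neither the counting tool, the annotation release nor any use of molecular identifiers is stated. The deposited normalized signal equals the raw count divided by 1 factor per library, with a relative spread within a library of at most 9.64e-15. This signal served for gene names and for a check of the factors only. The factors the authors' values imply lay between 0.976 and 1.02, and the TMM factors computed here divided by them gave 0.986 to 1.02. Every column of both tables matched 1 library, with 0 left unmatched.

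All computation started from the raw counts. The count table has 60669 genes, of which 32909 had no count in any library and 20052 carry no gene name. The filterByExpr function of edgeR, with its minimum count of 10 and the 6 groups, kept 11841 genes, which held at least 99.0% of the counts of every library. Library totals ran from 1599939 to 2180500 with a median of 1763934, and 17531 to 18841 genes had at least 1 count. A count of 3, taken as the floor of detection, corresponds to 1.38 to 1.88 CPM. The median standard error of a log2 change between an agonist and its vehicle was 0.16 over all tested genes and 0.10 above 64 CPM. Intervals on counts cover counting error only and leave out variation between libraries. They take reads as independent molecules, which is not known, since any use of molecular identifiers is not stated. Where reads are not independent, the intervals are too narrow. The biological coefficient of variation was 5.67%. Libraries of 1 group differed beyond sampling noise, with a chi-square per degree of freedom of 1.14 to 2.00.

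Differences were tested with the quasi-likelihood test of edgeR 4.0.16 (robust fit, TMM factors of 0.966 to 1.02, group means without a block) in R 4.3.3. All 18 libraries entered 1 fit with 12 residual degrees of freedom, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 11841 genes. The contrasts were each agonist against its own vehicle, the 3 differences between agonists in their log2 change from vehicle, and the 3 differences between control groups. No agonist shares control libraries with another. These contrasts, the tests and the alternatives were fixed before the data were examined, except where a later choice is stated.

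The 23 pathway lists and 5 lists of cell type markers were fixed in the same way. Lists with at least 3 tested members were tested with camera of limma 3.58.1, two-sided, with the inter-gene correlation preset at 0.01, adjusted over the 22 lists that qualified (the receptors of the agonists had 2 tested genes) and separately over the 2 marker lists that did. An estimated correlation and fry, a rotation test of whether a list's genes move one way on balance, were run as alternatives. Beside members called over all genes, the count adjusted over the list alone is given.

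Named genes follow a rule. In each agonist contrast these were the 15 largest rises and the 8 largest falls among called genes with a mean count of at least 10 in the higher group and no overlap between the 3 treated and the 3 vehicle libraries, which chance alone gives for 10% of genes. The rule also took up to 4 members of each pathway list by smallest p in any agonist contrast, and receptors of the agonists. Genes outside the rule are named as chosen after their values were seen. Where a vehicle count was near the floor, the ratio of the summed counts is given with its 95% counting interval. Gene positions come from GENCODE release 29 on GRCh38, in which all 160 identifiers looked up were found, 157 under the same symbol.

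Whether replicate numbers pair the libraries was decided from the correlation of deviations from group means, with all 3 pairs of an agonist and its vehicle required to exceed 0.1. The VIP pairs met this (0.228, 0.173 and 0.138). The Iso pairs (0.172, 0.0864 and 0.00835) and the NECA pairs (0.246, 0.0363 and 0.227) did not. A fit with the replicate number as a block is therefore given beside the VIP counts. Missing the rule does not show that the Iso and NECA libraries are unpaired. Over all groups, libraries of the same number deviated together (mean r 0.115), which the main fit leaves out. The block is for this reason given beside the Iso and NECA counts too.

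Alternatives were other size factors (RLE, library totals alone), no filter on low counts, a filter of 5 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate block, fits on the compared groups alone, stricter thresholds, the 9 controls as 1 group, and each library left out in turn. The filter of 5 CPM was meant to be stricter but kept 12124 genes, more than the main filter. In a test on simulated counts with 200 changed genes among 11701, edgeR recovered 44.1% of log2 changes of 0.5, 74.2% of changes of 1 and 100% of changes of 2 for NECA against its vehicle, with 8 false calls. For the difference between the NECA and Iso responses it recovered 23.5%, 59.1% and 95.5%, with 10 false calls. In the simulated list test for NECA, the shifted list was called, and 0 of the others were. Simulated genes varied independently and held no structure by replicate number, so this test could not show false list calls that arise from either.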

Results

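Messenger RNA was counted by 3' tag sequencing in 18 cultures of HEK293 cells, 3 for each of 3 agonists and 3 for the vehicle of each. The agonists act on receptors that raise cAMP: isoproterenol (Iso) on β-adrenergic receptors, NECA on adenosine receptors and vasoactive intestinal peptide (VIP) on VIP receptors. All treatments lasted 90 min by the labels, which give no time for the VIP control. Library totals lay between 1599939 and 2180500 counts, and a count of 3 equals 1.38 to 1.88 CPM. Mitochondrially encoded transcripts took 3.52 to 4.02% of the counts of a library, with group means from 3.79% for the VIP vehicle to 3.98% for NECA. In what follows, changes are log2 values ± SE of an agonist against its own vehicle, with n = 3 libraries per group, and levels are TMM-scaled CPM ± SD. The SE is the size of the log2 change over the square root of the F statistic of its test. For large rises from vehicle counts near the floor, such as those of PCK1 and NR4A3, this SE is too small.

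Some receptors of these agonists were measured in the 9 vehicle libraries. ADORA2B stood at 10.8 ± 2.88 CPM. VIPR1 (2.40 CPM, 63 counts in the 18 libraries) and ADRB1 (1.84 ± 1.08 CPM, 75 counts) lay close to the floor and were not tested. VIPR2 had 1 count in the 18 libraries together, and ADORA2A had 0, which allows no more than 1.38 to 1.88 CPM in a library. ADORA2B did not pass the test with any agonist (edgeR), at -0.07 ± 0.27 with Iso, -0.26 ± 0.25 with NECA and 0.41 ± 0.27 with VIP.

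Isoproterenol against ascorbic acid asked which transcripts the β-adrenergic agonist changed. PCK1, the gene of the gluconeogenic enzyme phosphoenolpyruvate carboxykinase, rose from 2.00 ± 1.08 to 84.5 ± 8.03 CPM, a log2 change of 5.34 ± 0.25. Its vehicle libraries held 2 to 6 counts each, and the ratio of summed counts was 41.8 (95% counting interval 23.2 to 84.4). The 3 NR4A genes, which encode orphan nuclear receptors, rose together: NR4A3 by 4.39 ± 0.27, NR4A1 by 3.08 ± 0.25 and NR4A2 by 3.03 ± 0.16, the last from 34.6 ± 1.31 to 284 ± 50.9 CPM. CGA, the common subunit of the glycoprotein hormones, rose by 2.29 ± 0.16, and AREG, a ligand of the EGF receptor, by 1.82 ± 0.27. The adjusted p of these 6 genes ran from 2.09e-23 for PCK1 to 4.69e-06 for AREG (edgeR).

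The other Iso rises among the 15 largest were these. INHBA, a subunit of activin, rose by 2.17 ± 0.41, DIO2, the deiodinase that activates thyroid hormone, by 1.87 ± 0.45, the granin SCG2 by 1.65 ± 0.34, neurotensin (NTS) by 1.41 ± 0.26 and the inducible cyclooxygenase PTGS2 by 1.48 ± 0.22. FOSB rose by 1.77 ± 0.38, ANKRD37 by 1.69 ± 0.33, TCIM by 1.40 ± 0.22 and BTG2 by 1.38 ± 0.13. DIO2 lost its call with DESeq2 (adjusted p = 0.162) and without any of 5 of the 6 libraries. FOSB lost it without Iso control replicate 1, Iso control replicate 3 or Iso replicate 2, and both ANKRD37 and SCG2 without Iso control replicate 1. RUNX1T1 (-0.48 ± 0.12, adjusted p = 0.0410) and HJURP (-0.47 ± 0.12, adjusted p = 0.0367), which encodes the chaperone of the centromeric histone CENPA, were the 2 genes called lower in the fit without a block, and each lost the call with DESeq2 (adjusted p = 0.245 and 0.199) and without any of 4 libraries.

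In all, 74 genes were higher and 2 lower with Iso among 11841 tested (edgeR), 24 of them by at least 1 log2 unit. DESeq2 called 55 higher and 0 lower, and limma-voom 71 and 2. The replicate block gave 98 higher and 6 lower, and the 9 controls as 1 group 123 genes. Without Iso control replicate 1, or without Iso control replicate 2, the count fell to 49.

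**Figure D1:**
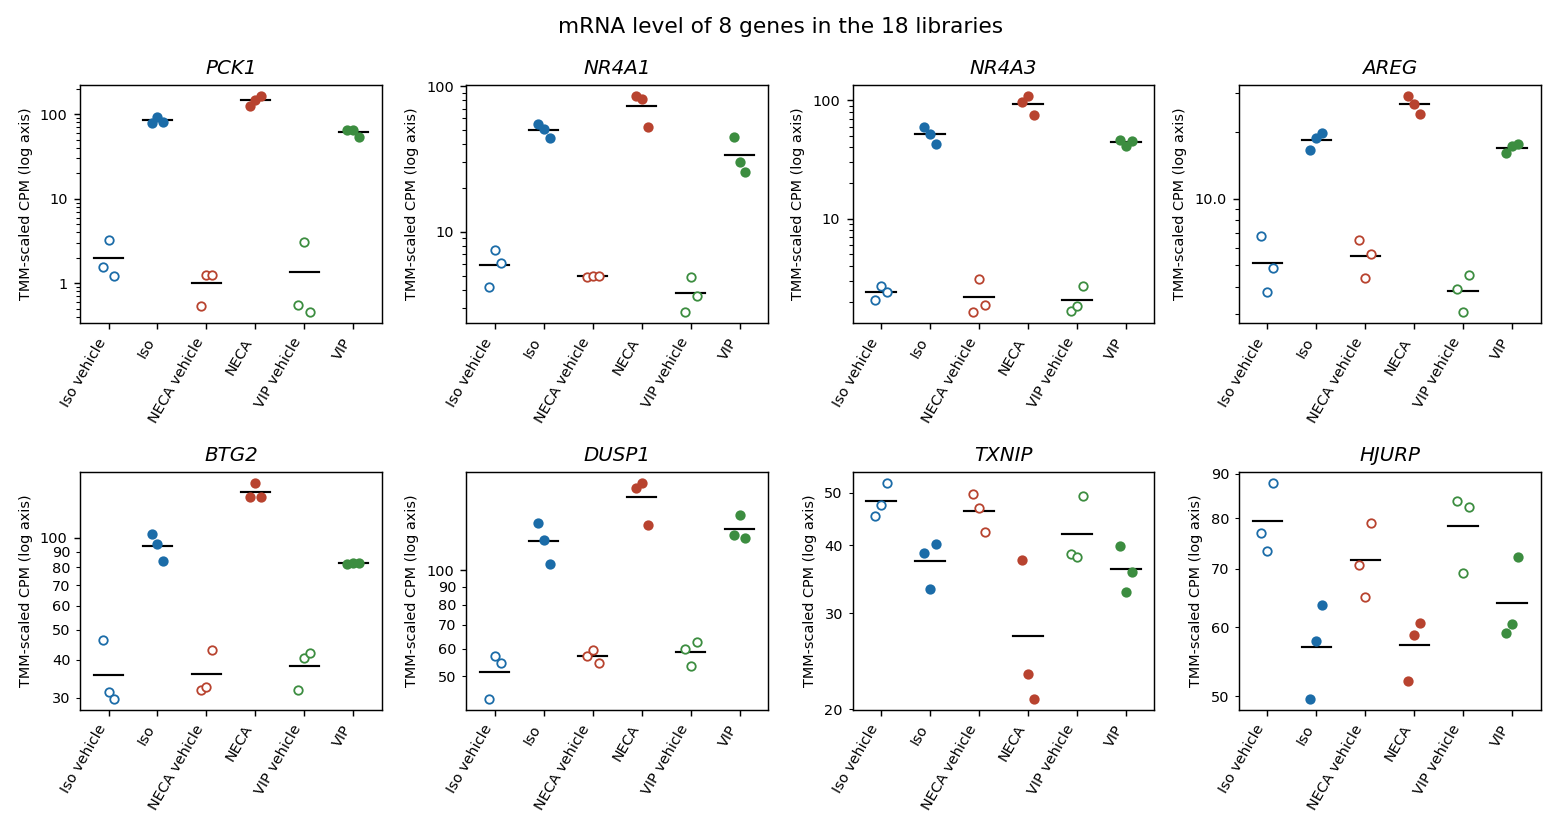
TMM-scaled CPM on log axes (which do not start at 0) for 8 genes in the 18 libraries. Open circles are vehicle libraries, filled circles agonist libraries, and bars the mean of 3 libraries; PCK1 stood at 1.01 to 2.00 CPM in the vehicle groups and 61.3 to 147 CPM with agonist, while TXNIP was called lower with NECA and HJURP with Iso.

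Among the gene lists, the CREB and cAMP-inducible genes moved most with Iso: 11 of 17 tested members rose, and 17 did so adjusted over the list alone. Besides the genes above, these included DUSP1, a phosphatase of MAP kinases (1.23 ± 0.12), RGS2 (0.85 ± 0.17), a regulator of G protein signalling, and CREM (0.67 ± 0.14), a CREB family member, whose call was lost without Iso control replicate 2 or Iso replicate 1. Of the immediate early genes, 8 of 21 rose (9 adjusted over the list alone), among them JUNB (1.05 ± 0.18), ATF3 (0.87 ± 0.10) and FOSL2 (0.80 ± 0.14). NR4A1, FOS, FOSB and BTG2 belong to both this list and the CREB list. EGR1 (0.31 ± 0.42) and JUN (-0.02 ± 0.08), both chosen after their values were seen, did not pass. Of the targets of SMAD proteins, 4 of 12 rose (6 adjusted over the list alone): ID1 (from 18.5 ± 4.48 to 37.7 ± 13.1 CPM), ID2 (0.56 ± 0.08), ID3 (0.49 ± 0.09) and PMEPA1 (0.41 ± 0.10), although ID1 lost its call without either of 2 libraries, PMEPA1 without any of the 6, and ID3 with the 9 controls as 1 group (0.28, adjusted p = 0.0712). Whether the Iso vehicle bears on this list is not settled. Between the NECA and Iso controls ID3 had the smallest p but did not pass. Camera called the list higher in the NECA control at the preset correlation, with adjusted p = 0.0662 with an estimated correlation.

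The feedback genes of the MAP kinase pathway were called with Iso through DUSP4 (0.95 ± 0.21) and DUSP6 (0.99 ± 0.24), 2 of 14 members (2 adjusted over the list alone). Both lost the call with DESeq2 and without any of 3 libraries. Feedback genes of the cAMP pathway were called through RGS2 and CREM, 2 of 18 members, with 4 adjusted over the list alone. Hypoxia-inducible genes had 1 of 16 members called (ANKRD37; 5 adjusted over the list alone), and the clock genes 0 of 13 (3 adjusted over the list alone), with PER1 at 0.91 ± 0.29 and PER2 at 0.90 ± 0.27. In the insulin and FOXO-responsive list PCK1 was the only member of 11 called (2 adjusted over the list alone), and the list's median was 0.02. The 18 genes of G2 and M phase fell as a list, with a median of -0.10 and 0 members called (0 adjusted over the list alone). These 9 lists were called by camera with the preset correlation (adjusted p from 5.73e-163 to 0.00708) and with an estimated one (7.84e-09 to 0.0209).

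A further 3 lists were called with Iso at the preset correlation alone. Cholesterol synthesis genes had 1 of 17 members called (3 adjusted over the list alone), INSIG1 at 0.66 ± 0.09, with adjusted p = 0.161 with an estimated correlation. Notch and Wnt targets had 1 of 14, the Notch feedback gene NRARP at 0.80 ± 0.11 (1 adjusted over the list alone), with adjusted p = 0.0810 with an estimated correlation. Ribosomal protein genes had 0 of 26 (0 adjusted over the list alone), with a median of 0.05 and adjusted p = 0.685 with an estimated correlation.

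NECA against DMSO asked the same of the adenosine agonist, which changed the most genes. PCK1 rose from 1.01 ± 0.41 to 147 ± 19.8 CPM, a log2 change of 7.11 ± 0.26. The vehicle libraries held 1 or 2 counts each, and the ratio of summed counts was 147 (counting interval 62.7 to 454). The SE of 0.26 is too small for a rise from so few counts. For PCK1 the difference between the NECA and Iso changes had an SE of 0.75. NR4A3 rose by 5.40 ± 0.24, NR4A1 by 3.88 ± 0.25 and NR4A2 by 3.64 ± 0.16, the last to 443 ± 47.7 CPM. FOSB rose by 3.16 ± 0.36, ANKRD37 by 2.95 ± 0.34, CGA by 2.42 ± 0.16, EGR3, an immediate early transcription factor, by 2.35 ± 0.42 and AREG by 2.26 ± 0.25. The adjusted p of these 9 genes was at most 1.31e-04 (edgeR).

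The remaining named rises with NECA were SCG2 (2.18 ± 0.33), AVPI1 (2.14 ± 0.37), NTS (2.02 ± 0.26), INHBA (1.99 ± 0.38), BTG2 (1.98 ± 0.13) and DIO2 (1.98 ± 0.39). Genes called lower included TXNIP, an arrestin-like protein that limits glucose uptake, from 46.3 ± 3.73 to 27.2 ± 9.10 CPM (-0.74 ± 0.17, adjusted p = 0.00614). They also included the zinc finger genes ZBED9 (-0.99 ± 0.24), ZNF182 (-0.96 ± 0.25), ZNF112 (-0.91 ± 0.25) and ZNF382 (-0.84 ± 0.22), the DNA glycosylase NEIL3 (-0.98 ± 0.25), TOX3 (-0.90 ± 0.21) and HOXA6 (-1.61 ± 0.42). Each of these 8 lost its call without at least 3 of the 6 libraries in turn, and all but TXNIP lost it with DESeq2.

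Of 11841 genes, 129 were higher and 16 lower with NECA (edgeR), 47 and 1 of them by at least 1 log2 unit. DESeq2 called 99 higher and 3 lower, and limma-voom 126 and 14. The number of falls moved with the fit: scaling by library totals alone gave 116 higher and 29 lower, and the replicate block 184 higher and 52 lower. With the 9 controls as 1 group 358 genes were called.

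With NECA, 14 of the 17 CREB and cAMP-inducible genes rose (15 adjusted over the list alone), adding to those above PDE4D (0.81 ± 0.16), a phosphodiesterase that degrades cAMP, BDNF (0.96 ± 0.24), CREM (from 35.6 to 72.0 CPM), RGS2 (0.99 ± 0.16), DUSP1 (from 57.2 to 161 CPM) and IRS2 (0.30 ± 0.07). IRS2 lost its call without NECA control replicate 2 or NECA replicate 3. FOS, at 1.65 ± 0.61, did not pass; FOS and BDNF were chosen after their values were seen. Of the immediate early genes, 9 of 21 rose (12 adjusted over the list alone), with JUNB at 1.98 ± 0.18, FOSL2 at 1.45 ± 0.14 and ATF3 at 1.10 ± 0.09. MAP kinase feedback genes had 3 of 14 members called (4 adjusted over the list alone), namely DUSP4 (1.48 ± 0.21), DUSP6 (1.31 ± 0.25) and IL11 (1.42 ± 0.28). Of the cAMP feedback genes 4 of 18 rose (6 adjusted over the list alone): CREM, RGS2, PDE4D and another phosphodiesterase gene, PDE10A (0.87 ± 0.17). SMAD targets had 2 of 12 called (3 adjusted over the list alone), PMEPA1 at 0.70 ± 0.10 and ID2 at 0.62 ± 0.08.

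Hypoxia-inducible genes had 3 of 16 called with NECA (3 adjusted over the list alone): ANKRD37, NDRG1 (0.80 ± 0.13) and the angiogenic factor VEGFA (0.65 ± 0.16), the last lost with DESeq2 and without any of 3 libraries. The insulin and FOXO-responsive list had 2 members higher, PCK1 and IRS2, and 1 lower, TXNIP, out of 11, with 3 higher and 4 lower adjusted over the list alone. Its test and its mean (0.51) pointed up while its median was -0.19, since PCK1 carried the mean. The 18 genes of G2 and M phase had a median of -0.13 and 1 called member, the centromeric histone CENPA (-0.69 ± 0.18), which lost its call with DESeq2 and without any of 4 libraries; 4 were lower adjusted over the list alone. These 8 lists were called with the preset correlation (adjusted p from 2.25e-182 to 0.00183) and an estimated one (3.47e-09 to 0.0113). Cholesterol synthesis genes (2 of 17, INSIG1 at 0.94 ± 0.09 and IDI1 at 0.50 ± 0.09; 3 adjusted over the list alone) had adjusted p = 0.114 with an estimated correlation. The 13 mitochondrially encoded genes (median 0.11, 0 members, 0 adjusted over the list alone) had adjusted p = 0.522 with an estimated correlation. The mitochondrial share of NECA libraries averaged 3.98% against 3.91% in their vehicle.

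VIP against its control asked the same of the peptide. PCK1 rose from 1.36 ± 1.48 to 61.3 ± 6.81 CPM, a log2 change of 5.55 ± 0.30 and a ratio of summed counts of 49.4 (counting interval 23.7 to 124). NR4A3 rose by 4.34 ± 0.28, NR4A1 by 3.16 ± 0.30, NR4A2 by 2.79 ± 0.16, AREG by 2.10 ± 0.29 and CGA by 1.98 ± 0.16. PTGS2 (1.32 ± 0.20), DUSP1 (1.15 ± 0.11), BTG2 (1.10 ± 0.13), TCIM (1.10 ± 0.23), ZKSCAN2 (1.10 ± 0.18), C11orf96 (1.01 ± 0.11), CD55, a complement regulator (0.98 ± 0.16), FOSL2 (0.90 ± 0.14) and RHOB, a small GTPase (0.90 ± 0.12), made up the 15 largest rises. TCIM lost its call without VIP control replicate 2 or VIP replicate 3 (adjusted p up to 0.0571).

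With VIP 42 genes were higher and 0 lower among 11841 (edgeR; 624 at an unadjusted p under 0.05), 12 of them by at least 1 log2 unit. DESeq2 called 38 and 0, limma-voom 41 and 0. The 9 controls as 1 group gave 95 called genes. With the replicate number as a block, which the VIP pairs call for, 69 were higher and 2 lower, and all 42 were among the 71. The genes added by the block, chosen after their values were seen, included the matricellular genes CCN1 (0.52 ± 0.08) and CCN2 (0.42 ± 0.06), SCG2 (1.39 ± 0.36) and, among the lower, FAM83D (-0.43 ± 0.11). CCN2 itself differed between replicate numbers 2 and 1 (0.54 ± 0.04), and CCN1 did too (0.32 ± 0.06).

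Of the CREB and cAMP-inducible genes 8 of 17 rose with VIP (13 adjusted over the list alone). CREM stood at 0.22 ± 0.14 and FOSB at 1.12 ± 0.40, neither called. Immediate early genes had 5 of 21 called (10 adjusted over the list alone), with ATF3 at 0.59 ± 0.10 and JUNB at 0.90 ± 0.19, the latter lost without VIP control replicate 1 or VIP replicate 3. SMAD targets had 1 of 12 (6 adjusted over the list alone), ID2 at 0.50 ± 0.08. MAP kinase feedback genes had 0 of 14 (2 adjusted over the list alone), with IL11 at 1.08 ± 0.29 and DUSP6 at 0.11 ± 0.26. Clock genes had 0 of 13 (2 adjusted over the list alone), hypoxia-inducible genes 0 of 16 (3 adjusted over the list alone), and the insulin and FOXO-responsive list 1 of 11, PCK1, with a median of 0.01 (2 adjusted over the list alone). These 7 lists were called with the preset correlation (adjusted p from 4.51e-133 to 0.00523) and an estimated one (1.62e-08 to 0.0339).

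Cholesterol synthesis genes (1 of 17 called with VIP, INSIG1 at 0.61 ± 0.09; 3 adjusted over the list alone) had adjusted p = 0.247 with an estimated correlation, and ribosomal protein genes (0 of 26; 0 adjusted over the list alone) adjusted p = 0.575 with an estimated correlation. The cAMP feedback list was not called (adjusted p = 0.0701), though its member PDE10A rose by 0.89 ± 0.17. With the replicate block, 4 more VIP lists passed at the preset correlation: targets of YAP and TEAD (adjusted p = 0.0441), targets of SRF and MRTF (0.0384), Notch and Wnt targets (0.0426) and, as a fall, genes of G2 and M phase (0.0260). Their adjusted p values with an estimated correlation were 0.192, 0.0740, 0.0803 and 0.0589.

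**Figure D2:**
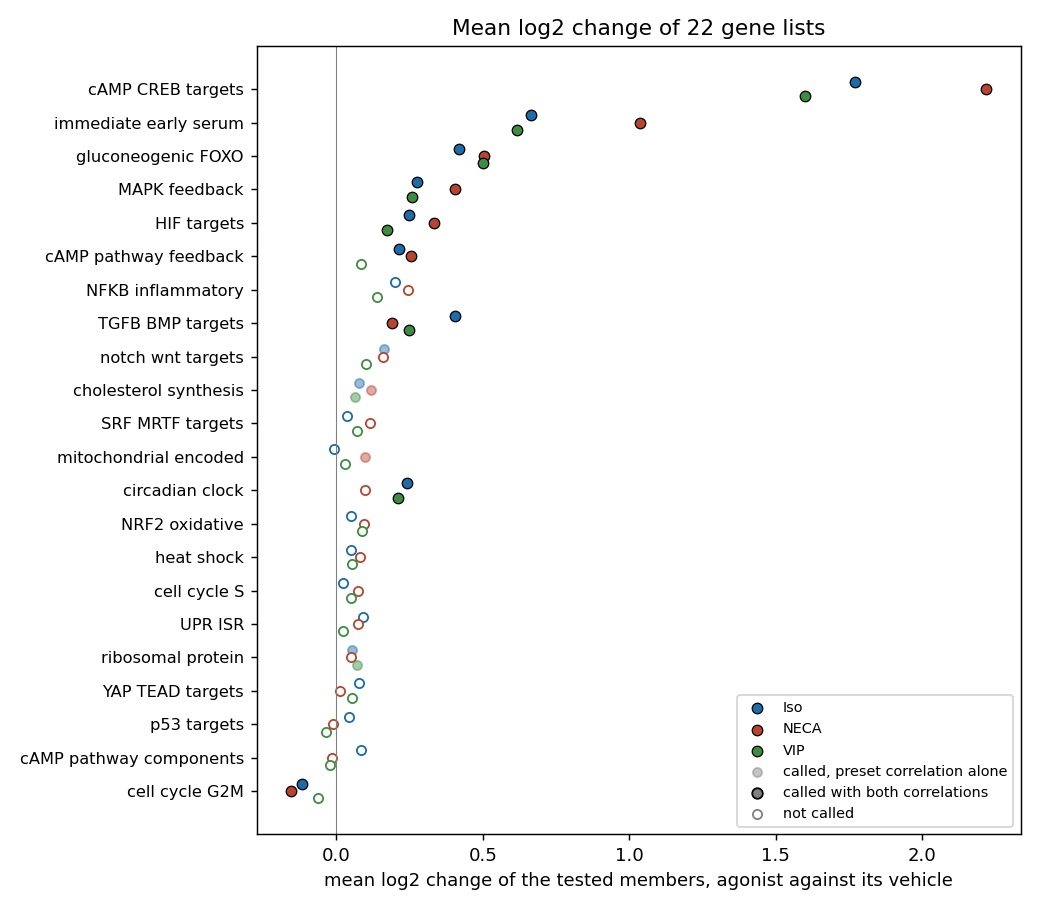
Mean log2 change of the tested members of 22 gene lists for each agonist against its own vehicle. Filled circles with a black edge were called with the preset and the estimated correlation, pale circles with the preset one alone, and open circles by neither; CREB and cAMP-inducible genes averaged 1.77 with Iso and 2.22 with NECA.

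The lists that camera with the preset correlation called with no agonist in the fit without a block were the components of the cAMP pathway (22 tested genes), targets of YAP and TEAD (21), targets of SRF and MRTF (17), NF-kB targets (7), unfolded protein response genes (15), heat shock genes (12), p53 targets (12), NRF2 targets (11) and S phase genes (18), the smallest adjusted p among them being 0.0560 for the unfolded protein response with Iso. Of these, fry called the unfolded protein response higher with Iso (median 0.07, adjusted p = 0.00612) and NECA (0.05, 0.0157) and the components of the cAMP pathway higher with Iso (0.05, 0.0319). Single members were called all the same: the apoptotic gene PMAIP1 rose by 0.34 ± 0.07, 0.54 ± 0.07 and 0.40 ± 0.07 with Iso, NECA and VIP, CCN1 by 0.89 ± 0.16 with NECA, and RRM2 by 0.27 ± 0.07 with NECA, the last lost with DESeq2 and without any of 4 libraries. Notch and Wnt targets were not called with NECA (adjusted p = 0.0990) or, unblocked, with VIP (0.0520), with NRARP at 0.87 ± 0.11 and 0.55 ± 0.11. NRARP lost its VIP call without VIP control replicate 2 or VIP replicate 1. Clock genes were not called with NECA (adjusted p = 0.333), where NFIL3 rose by 0.62 ± 0.15, a call lost with DESeq2 and without NECA control replicate 1 or NECA replicate 1. Mitochondrially encoded genes were not called with Iso (adjusted p = 0.602) or VIP (0.492), ribosomal protein genes not with NECA (0.112), and genes of G2 and M phase, unblocked, not with VIP (0.0535), although fry called the last as a fall (median -0.04, adjusted p = 0.0196).

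Of the marker lists, the neurofilament and neuroendocrine genes that HEK293 cells express were called higher with all 3 agonists (adjusted p with an estimated correlation 0.00444 with Iso, 0.00694 with NECA and 0.00678 with VIP). Of its 6 tested members NEFL, a neurofilament subunit, rose with Iso (0.49 ± 0.10) and NECA (0.51 ± 0.10), and CHGB, a granin of secretory vesicles, rose with NECA (1.88 ± 0.49). With Iso 2, with NECA 3 and with VIP 2 members were higher adjusted over the list alone. VIM stood at 0.03 ± 0.06, -0.02 ± 0.06 and 0.09 ± 0.06. Epithelial markers (4 tested) were not called, the smallest adjusted p being 0.514. Fibroblast markers had 2 tested genes, COL1A1 and FBLN1, neither called. Blood and endothelial markers had 0 tested genes, and their most abundant members averaged 0.936 CPM (CD14) and 2.89 CPM (ESAM). The single markers were chosen after their values were seen.

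The overlap of the 3 responses bears on whether the agonists change the same genes. PCK1, NR4A1, NR4A2, NR4A3, CGA, AREG, BTG2, DUSP1, PTGS2, INSIG1 and ID2 were among the 39 genes called higher with all 3, and each of the 39 had its largest fold with NECA. Iso and NECA shared 69 rises, where independent lists of the same lengths would share 0.806. Iso and VIP shared 39 (0.262), and all 42 VIP rises were among those of NECA (0.458), all in the fit without a block. With the replicate block NECA held 65 of the 69 VIP rises, and Iso 61. In the fit without a block no fall was shared, that is 0 between any pair, and 0 genes were called in opposite directions, while with the block Iso and NECA shared 3 falls, Iso and VIP 1 and NECA and VIP 1. Together, unblocked, 134 genes were higher and 18 lower with at least 1 agonist.

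Across the genes called with either agonist of a pair, log2 changes correlated at r = 0.937 for Iso and NECA (152 genes), 0.957 for Iso and VIP (79 genes) and 0.904 for NECA and VIP (145 genes), with Spearman's rho of 0.880, 0.871 and 0.839. Jackknife standard errors over libraries were 0.0396, 0.0487 and 0.0839. Genes are not independent replicates, and those called were chosen for a large change. Over all 11841 genes r was 0.372, 0.289 and 0.372, and 100 regroupings of the libraries within each agonist and its vehicle gave values from -0.230 to 0.230, -0.197 to 0.161 and -0.201 to 0.200.

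**Figure D3:**
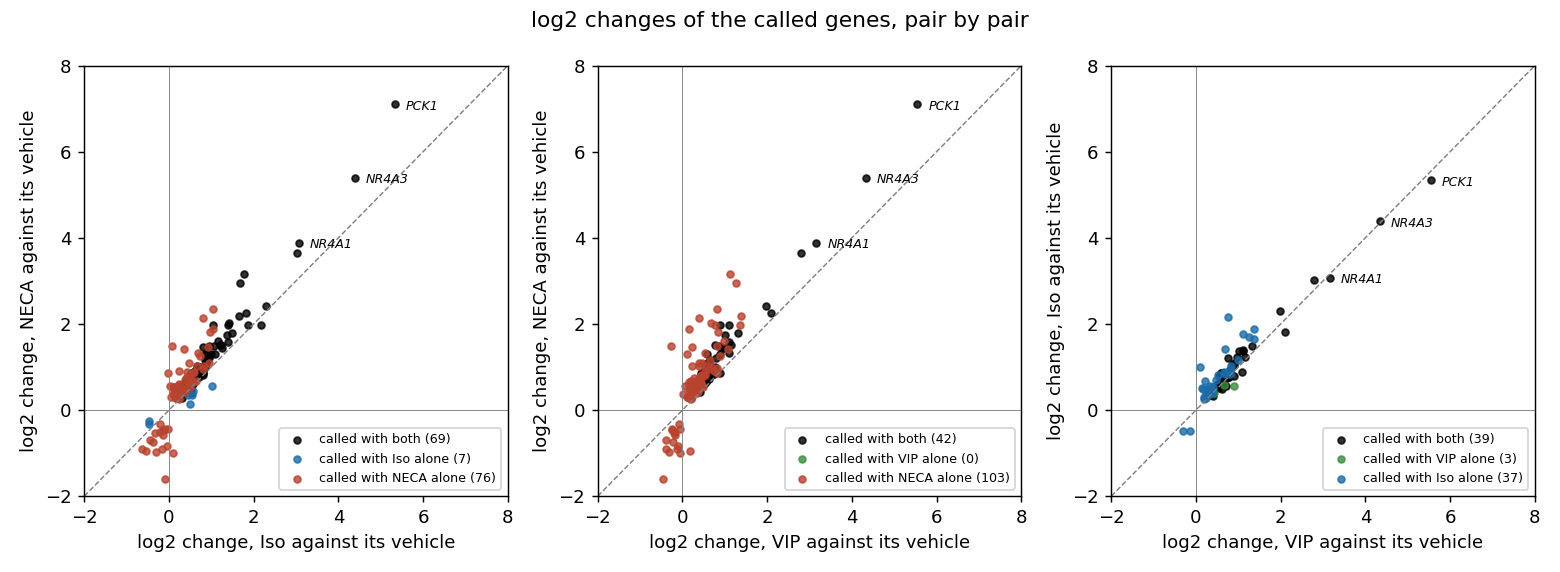
log2 changes against vehicle for the genes called with either agonist of each pair, with the dashed line marking equal changes. NECA is on the vertical axis of the left and middle panels and Iso on that of the right one; PCK1 lies at 7.11 with NECA, 5.34 with Iso and 5.55 with VIP.

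Whether the agonists differ was tested gene by gene on the difference between their changes from vehicle, and no gene passed in the fit without a block. NECA minus Iso, VIP minus Iso and VIP minus NECA each gave 0 genes with edgeR, DESeq2 and limma-voom, with 420, 336 and 415 genes at an unadjusted p under 0.05 (edgeR). The median standard error of a difference was 0.23, 0.22 and 0.23, and 0.14 in each above 64 CPM. The smallest adjusted p, 0.166, was that of VIP minus NECA for C11orf96 (-0.74, 95% interval -1.09 to -0.39) and BTG2 (-0.88, -1.30 to -0.46). The naming rule took both genes in agonist contrasts, but for this contrast they were chosen after their values were seen. JUNB differed by 0.94 between NECA and Iso (0.34 to 1.53) and PCK1 by 1.77 (0.14 to 3.40), with adjusted p = 1.00 for each.

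With the replicate number as a block, 7 genes passed for VIP minus NECA, all lower: NR4A2 (-0.87 ± 0.17), BTG2 (-0.88 ± 0.18), C11orf96 (-0.73 ± 0.15), SLC2A3 (-0.74 ± 0.16), ZNF331 (-0.64 ± 0.12), SYAP1 (-0.38 ± 0.08) and ATP1B3 (-0.44 ± 0.09), with adjusted p from 0.0124 to 0.0201. The block left the counts for NECA minus Iso and VIP minus Iso as above. With no filter on low counts, 5 genes passed for VIP minus NECA: NR4A2 (-0.85 ± 0.16), BTG2 (-0.88 ± 0.18), C11orf96 (-0.74 ± 0.16), SLC2A3, a glucose transporter (-0.74 ± 0.16), and ZNF331 (-0.63 ± 0.13). Without NECA replicate 1 the gene C11orf96 passed (-0.83 ± 0.16), and without NECA replicate 3 the gene ZNF331 (-0.73 ± 0.14). ATP1B3, SLC2A3, SYAP1 and ZNF331 were chosen after their values were seen.

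**Figure D4:**
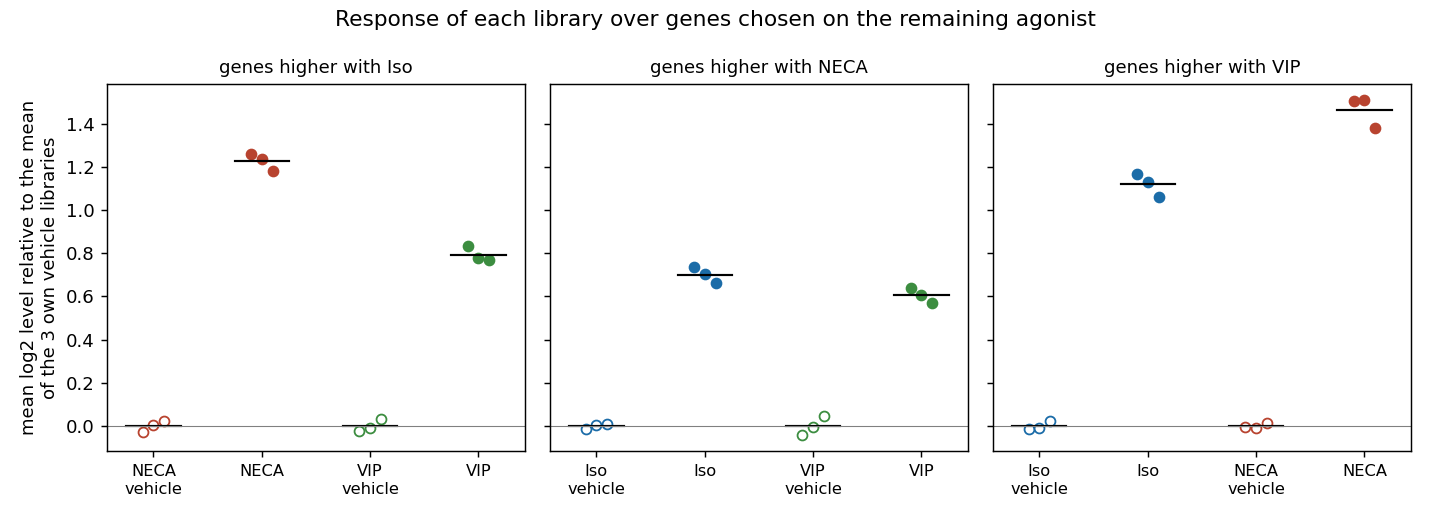
Mean log2 level of each agonist library relative to the mean of its own vehicle, over the genes called higher with the agonist not shown in that panel; bars are means of 3 libraries. Over the 74 genes called higher with Iso the NECA libraries stood at 1.26, 1.24 and 1.18 and the VIP libraries at 0.83, 0.78 and 0.77.

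The control groups serve as background for these comparisons. Between NECA and Iso controls, VIP and Iso controls, and VIP and NECA controls 0 genes differed with edgeR, DESeq2 and limma-voom, with 356, 307 and 365 at an unadjusted p under 0.05 (edgeR). The genes with the smallest p, chosen after their values were seen, were ID3 (0.35 ± 0.09 between the NECA and Iso controls), EHD1 (-0.61 ± 0.18 between the VIP and Iso controls) and PIGH (0.75 ± 0.19 between the VIP and NECA controls). Camera with the preset correlation called 2, 0 and 1 lists there, and 0 in each with an estimated correlation.

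The genes with the largest changes lie on several chromosomes (GRCh38, start to end of the annotated gene). PCK1, identifier ENSG00000124253.11, spans 57561080 to 57568112 on chromosome 20. NR4A1 (ENSG00000123358.20) spans 52022832 to 52059507 on chromosome 12, NR4A2 (ENSG00000153234.14) 156324432 to 156342348 on chromosome 2 and NR4A3 (ENSG00000119508.18) 99821855 to 99866891 on chromosome 9. CGA (ENSG00000135346.8) spans 87085498 to 87095406 on chromosome 6, AREG (ENSG00000109321.11) 74445134 to 74455009 on chromosome 4, and TXNIP (ENSG00000265972.6) 145992435 to 145996600 on chromosome 1. All are annotated as protein-coding.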

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

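The contrasts of response size over genes taken as a set, their tests with thinned libraries and with single libraries left out, and the estimated correlation and fry for differences between responses were chosen after the results were seen.

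The genes that rose with 1 agonist were used to compare the size of the response to the other 2, so that neither of the compared agonists chose the genes. Over the 74 genes called higher with Iso, among them PCK1, the NR4A genes, CGA and AREG, the median of VIP minus NECA was -0.339 on the log2 scale (medians 0.613 with VIP and 0.924 with NECA). VIP lay below NECA for 71 of the 74 genes (fry, adjusted p = 5.74e-06). Over the 42 genes called higher with VIP the median of NECA minus Iso was 0.285 (1.13 against 0.828; 42 of 42 genes, adjusted p = 1.80e-04). Over the 129 genes called higher with NECA the median of VIP minus Iso was -0.0758 (93 of 129 genes lower, adjusted p = 0.0282). What marked these values is a difference between groups in the size of the same response.

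Several technical explanations of the smaller VIP than NECA response were tested. With every library thinned to the lowest total the median was -0.358, which argues against depth. Between the treated libraries alone it was -0.351, with VIP lower for 74 of 74 genes, and between the vehicle libraries alone 0.0111, which argues against unlike vehicles. Leaving out each library in turn gave -0.379 to -0.316, so no single library carries it. When agonist identity was regrouped within the 6 treated and within the 6 vehicle libraries, 3 of 100 regroupings gave a median as far from 0 as the real -0.339. The highest of the others was 0.383, and all 3, the real one included, keep the real treated groups. Over all 100 the share of 3 excludes chance at the level of 0.05 only, and most of the regroupings do not balance the replicate numbers. Of the 12 that do, 1, the real one, gave as much, and 12 are too few for a share under 0.05. For NECA against Iso 2 of 100 regroupings gave as much (real 0.285, highest other 0.308), each with the real treated groups. Of the 12 balanced ones 1 did, the real one. The same limit therefore holds for excluding chance. For VIP against Iso 9 of 100 (real -0.0758, highest other 0.108) do not exclude it, although 6 of these 9, the real grouping among them, keep the real treated groups, and the p of that difference exceeded 0.05 on leaving out any of 7 of the 12 libraries (p up to 0.146).

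A candidate explanation is a weaker response to VIP than to NECA, found and tested on the same libraries and seen between the treated libraries alone (-0.351). It stays open whether this reflects the agonist, its dose or the time point, since each agonist was given at 1 dose for 1 time. Receptor abundance was not tested as a cause.

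A single scale factor between responses was tested as a hypothesis. For NECA and Iso the ratio was 1.30 (95% interval 1.25 to 1.36), and the residuals of the 42 genes had a chi-square per degree of freedom of 0.744, so 1 factor may describe them. For VIP and Iso the ratio was 0.889 (0.849 to 0.930), with 0.888. These intervals run over genes and leave out variation between libraries, so that of VIP and Iso does not show a difference. For VIP and NECA the ratio was 0.674 (0.645 to 0.703), with 1.46 against an upper limit of 1.35. This does not decide against 1 factor for all 74 genes. The residuals were divided by SEs that are too small for large rises from counts near the floor. With VIP, CREM, DUSP6 and NTS lay below what the factor gives. PCK1 and NR4A3 lay above it, but both are such rises.

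Gene lists differed between responses by camera with the preset correlation, again a difference between groups. Between NECA and Iso these were CREB and cAMP-inducible genes (median difference 0.31, adjusted p = 8.53e-05), immediate early genes (0.15, 2.57e-05) and mitochondrially encoded genes (0.14, 0.0109). Only the immediate early genes held with an estimated correlation (adjusted p = 0.00993) and with fry (0.0284), against 0.0800 and 0.188 for the CREB list and 0.702 and 0.748 for the mitochondrial one. The immediate early and CREB lists share NR4A1, FOS, FOSB and BTG2, so their results are not independent. Between VIP and NECA they were CREB and cAMP-inducible genes (-0.42, 2.50e-10), immediate early genes (-0.14, 1.51e-07), cAMP feedback genes (-0.15, 0.0200) and genes of G2 and M phase (0.10, 0.0498). The CREB list (adjusted p = 0.00438 with an estimated correlation) and the immediate early genes (0.00255) held, while the cAMP feedback genes and those of G2 and M phase had adjusted p = 0.0906 each. With fry the adjusted p was 0.0132 for the CREB list, 0.00749 for the immediate early genes, 0.0865 for the cAMP feedback genes and 0.0429 for those of G2 and M phase.

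Chance is not excluded for these list counts. Of 100 regroupings, 43 gave at least the 3 lists of NECA minus Iso (highest other 7) and 36 at least the 4 of VIP minus NECA (highest other 8). Most of these regroupings do not balance the replicate numbers, which carry a structure of their own. Of the 12 that do, 2 and 3 gave as many, the real one included, and 12 are too few for a share under 0.05. A real count of 0 is reached by 100 of 100 regroupings whatever the data, so the lists of VIP minus Iso (highest other 7) and the genes of all 3 differences decide nothing, with a highest other of 13 for NECA minus Iso, 8 for VIP minus Iso and 216 for VIP minus NECA. The regrouping with 216 sets NECA replicate 1, VIP replicate 1 and VIP replicate 3 with NECA control replicate 3, VIP control replicate 2 and VIP control replicate 3, which parts the vehicle libraries numbered 1 from treated ones numbered 1 and points to a structure by replicate number.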

How the results depend on the processing

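The alternatives for the averaged contrast and for response size, and the estimated correlation and fry for differences between responses, were chosen after the data were seen; the others were chosen before. Of the alternative values of counts, lists, correlations and response sizes, 269 stayed the same, 26 moved, 8 fell below the threshold and 0 reversed. A count of genes or lists stayed the same within 1.5 times, and a correlation within 1 jackknife standard error. A response size did so if it kept its direction and its side of the threshold. Of 111 called values of named genes, 84 kept the call without each library in turn and 0 reversed under any alternative; 27 lost the call without at least 1 library and 18 under another alternative. With a log2 change of at least 1 in size, 24, 48 and 12 genes were called for Iso, NECA and VIP, by construction. With the replicate block NECA gave 236, VIP 71, VIP minus NECA 7 (SLC2A3, ATP1B3, ZNF331, NR4A2, BTG2, SYAP1 and C11orf96) and the averaged contrast (genes changed, 3 agonists averaged) 487, and 62 called genes were shared by Iso and VIP and 66 by NECA and VIP; all unblocked calls of the 3 agonists were kept. With the 9 controls as 1 group the counts were 123, 358 and 95, the cause was not tested. Without a filter VIP minus NECA gave 5 genes, the cause was not tested. DESeq2 gave 194 in the averaged contrast, the cause was not tested. With an estimated correlation 1 list differed for NECA minus Iso and 2 for VIP minus NECA, and with fry 1 for NECA minus Iso. Over all genes r was 0.372, 0.289 and 0.372 (the cause was not tested), and Spearman's rho over called genes was 0.880 and 0.871 for Iso with NECA and VIP. With library totals alone the smaller VIP than Iso response (response size, genes chosen on the third agonist, VIP minus Iso) was -0.0787 and no longer passed, the cause was not tested. Leaving out 1 library, which leaves a group of 2, gave 49 to 66 genes for Iso (49 without Iso control replicate 1 or Iso control replicate 2), 0 to 1 for VIP minus NECA and -0.102 to -0.0598 for the response size of VIP minus Iso. Small changes were often missed at this depth, spread and group size: in simulated counts 44.1% of log2 changes of 0.5 were recovered for NECA and 23.5% for the difference between NECA and Iso.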

Other observations

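The contrast of the 3 agonists averaged against their vehicles with its alternatives, and the test of rises and falls under another scaling, were chosen after the results were seen.

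Averaged over the 3 agonists (n = 9 against 9), the genes called lower included CENPA (-0.52 ± 0.10), KIF18A (-0.44 ± 0.09), FAM83D (-0.42 ± 0.07), HJURP (-0.37 ± 0.07) and GAS2L3 (-0.36 ± 0.08). The list of G2 and M phase had a median of -0.08, 3 of 18 members called lower (4 adjusted over the list alone) and adjusted p = 0.00223 with an estimated correlation. TXNIP (-0.44 ± 0.09) and the coagulation factor F3 (-0.51 ± 0.14) were lower too. FOS (1.46 ± 0.38), JUNB (1.31 ± 0.11) and the tachykinin gene TAC1 (adjusted p = 7.76e-05) were higher. In all 229 genes were higher and 63 lower (edgeR), 172 and 22 with DESeq2, 226 and 62 with limma-voom, and 343 and 144 with the replicate block. Of 100 regroupings within each agonist and its vehicle, 1, the real one with 292 genes, gave as many, the highest other being 158. This share of 1 in 100 argues against chance for the total only, in which the 229 rises outnumber the 63 falls. The falls were not regrouped on their own, so chance is not excluded for them. How far these regroupings balance the replicate numbers was not examined. All genes named here were chosen after their values were seen.

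More genes rose than fell. With NECA 89.0% of calls were rises and in the averaged contrast the median rise was 0.44 and the median fall -0.29. Less power at low counts would leave the shares even among abundant genes, yet above 64 CPM 79.0% of averaged calls were rises. With library totals alone 80% of the NECA calls were rises, which argues against scaling as the whole cause. No biological explanation was tested.

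Libraries with the same replicate number deviated together from their group means (mean r 0.115). The mean r of -0.0576 for different numbers follows from this, since the 3 deviations of a group sum to 0. Of 1001 different numberings within groups 2 gave a mean as high, the real one and 1 other at 0.117, and 2 of 1001 with every library thinned to the lowest total (0.105, highest other 0.106), so chance numbering and depth are excluded. Between numbers 2 and 1, 522 genes differed, between 3 and 1, 459, and between 3 and 2, 17. HSPA1A stood at 164 ± 15.2, 218 ± 16.4 and 286 ± 27.1 CPM in the 6 libraries of numbers 1, 2 and 3, and ANKRD1 at 92.5 ± 9.74, 189 ± 23.3 and 124 ± 15.7 CPM, both chosen after their values were seen. Heat shock genes differed as a list in all 3 pairs of numbers (camera, adjusted p with an estimated correlation 3.89e-04, 3.13e-05 and 0.0179). Between numbers 3 and 2, however, the list's median was 0.01 and 2 of 12 members were called, against 9 in each other pair. Targets of SRF and MRTF and of YAP and TEAD were higher in number 2 than in number 1 (6.31e-05 and 0.00837) and lower in number 3 than in number 2 (1.77e-05 and 9.82e-04). Numbers that share a culture, a day or a preparation are a candidate explanation for the r of 0.115; the labels name none of these, and no biological explanation was tested.

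For each agonist the 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05, and 1 of 10 gave as much as the real split in each of 6 counts. Genes numbered 76 for Iso (highest other split 1), 145 for NECA (2) and 42 for VIP (3), and lists 12 (6), 10 (6) and 9 (7). Between controls the count was 0 in each pair (edgeR, DESeq2 and limma-voom; 356, 307 and 365 at an unadjusted p under 0.05), so 10 of 10 splits gave as many, with a highest other of 0, 0 and 4.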
